A study of Mus musculus with 6 samples.

How the data were processed

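RNA was extracted with Trizol from Neuro2A cells transfected with si-NC or an siRNA against circCpsf6 at 100 nM with a lipid reagent, and sequenced on an Illumina platform, per the labels' protocols. The labels name a small RNA preparation kit for the mRNA libraries, and strand handling is not given in the sources used here. The authors deposited 1 table for the series, with a value per gene in each of the 6 libraries. Those values are FPKM rounded to 2 decimals, per the file headers. The same table holds the authors' fold change as a ratio and their log2 fold change. The latter equals the log2 ratio of group mean FPKM within 0.009 in 11448 genes with values above 1 in all libraries. It also holds p-values and q-values, per the file headers. The test behind the p-values and the program that computed FPKM are not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9, without a role. In all, 55144 gene identifiers of the table were found in the GENCODE M21 annotation of GRCm38, which was used here for positions, gene classes and sequences. All coordinates are in GRCm38.

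FPKM are relative values, so a gene's value depends on the rest of its library, and counts behind a value are not known. Depth was estimated from the steps between low values of genes with transcripts of 150 to 1500 bases. The implied depth was 14900000, 15600000 and 18800000 fragments for si-NC replicates 1 to 3 and 17500000, 17600000 and 14600000 for si-circCpsf6. Because at most 35.9% of low values were whole multiples of a step within 0.1, no count test was run, and values near 0 have an unknown counting error. Pearson correlations of log2(FPKM + 1) across tested genes, which are not independent replicates, were 0.936 to 0.971 between libraries of the same group and 0.919 to 0.949 between groups. The first principal component held 38.1% of the variance and parted the 2 groups, and the second held 22.9% and set si-circCpsf6 replicate 1 (26.5) against si-circCpsf6 replicate 2 (-32.3).

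Groups and replicate numbers came from the sample titles. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12974 genes). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend in the prior variance, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. An exact permutation test of 3 against 3 cannot give a p below 0.1, so no gene was tested that way. On simulated data with 200 of 12974 genes changed, the test recovered 45.9% of 2-fold and 89.7% of 4-fold changes in the right direction, and 5.4% and 5.9% of its calls were false. The simulated noise was normal and independent between genes, with no shift of a whole library. These shares therefore need not hold for the real libraries.

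Before the data were examined, 37 gene lists were fixed, including markers of other cell types, and those with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation. Annotation terms given in the table with 10 to 300 tested genes were tested likewise. Genes are named by a rule fixed at the same time: Cpsf6, the 12 largest rises and 12 largest falls among called genes with non-overlapping groups, the 5 smallest p-values in each direction, and members of each list. For each list these are up to 4 members past the test or, where none passed, up to 2 with the smallest unadjusted p. Genes outside the rule are named only as overlapping neighbours or copies of such genes, or where the text says that they were chosen or named after their values were seen.

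Alternatives were median centring, quantile normalization, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM and limma without the trend. Further alternatives were the replicate number as a block, protein-coding genes alone, an absolute log2 fold change of at least 1, the authors' own calls and q-values, and leaving out each library in turn. A fit without genes carrying a 3' UTR heptamer was added after the data were examined.

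The heptamer search used the longest annotated 3' UTR of each tested gene, with at least 50 bases (10668 genes). Log2 fold changes were regressed on UTR length, base composition and mean expression, and the residual ranks of genes with and without each heptamer present in at least 30 genes were compared as a rank z. With fold changes shuffled over genes a single time, the most negative z was -3.67, and both of 2 planted effects were recovered. Intervals of medians came from 2000 bootstrap draws over genes. Sequence work and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.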

Results

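Gene expression was profiled in mouse Neuro2A cells, a neuroblastoma line labelled as neuroblasts, after transfection with a small interfering RNA (siRNA) against circCpsf6 (si-circCpsf6, n = 3) or with the comparison siRNA si-NC (n = 3). CircCpsf6 is a circular RNA named for its host gene Cpsf6, which encodes a subunit of the cleavage factor that binds pre-mRNA before polyadenylation. The deposited table gave 1 FPKM value (fragments scaled by transcript length and by the fragments mapped in a library) per annotated gene and library. Between 12671 genes (si-NC replicate 3) and 13080 genes (si-circCpsf6 replicate 3) reached 1 FPKM. Steps between low values, searched within preset bounds, implied about 14600000 to 18800000 fragments per library. Only 31.0% to 35.9% of those values were whole multiples of a step within 0.1, some of them by chance, so read counts were not recovered. Mitochondrially encoded protein-coding genes took up to 20.6% of summed FPKM in si-NC and up to 18.5% in si-circCpsf6, with overlapping ranges. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

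The host gene was examined first. Cpsf6 (ENSMUSG00000055531, chromosome 10, 117344673 to 117380015, GRCm38) was at 14.6 ± 0.56 FPKM in si-NC and 13.4 ± 2.4 FPKM in si-circCpsf6 (mean ± SD, n = 3 each). The log2 fold change was -0.13 with a standard error of 0.15 and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.688). The si-circCpsf6 libraries read 10.65, 15.06 and 14.5 FPKM, and without replicate 1 the log2 fold change was 0.02. A value per gene does not separate the circle from the linear mRNA, so it neither checks the knockdown nor measures the circle, and no value is given for circCpsf6.

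The comparison of si-circCpsf6 with si-NC asked which genes responded to silencing of the circle. Of 12974 genes with a mean of at least 1 FPKM, 117 were higher and 102 were lower in si-circCpsf6 at an adjusted p under 0.05 (limma on log2(FPKM + 1)). Scg5, the chaperone of prohormone convertase 2 in neuroendocrine secretory granules (chromosome 2, 113776362 to 113829121, GRCm38), had the smallest p and fell from 108 ± 13.9 FPKM to 7.71 ± 2.7 FPKM, a log2 fold change of -3.68 ± 0.23 (SE, n = 3; limma adjusted p = 0.00445). A second granule gene fell, Vgf, a neuropeptide precursor, from 71.0 ± 17.55 to 16.0 ± 11.6 FPKM (limma adjusted p = 0.0486). Syt1, the calcium sensor of synaptic vesicle fusion, fell from 34.9 ± 1.61 to 10.3 ± 2.23 FPKM (limma adjusted p = 0.0134). Lancl1, a glutathione-binding protein of neurons (chromosome 1, 67000517 to 67038872), fell from 5.64 ± 0.22 to 1.03 ± 0.08 FPKM, and Gsr, which regenerates reduced glutathione, fell from 33.2 ± 3.28 to 9.9 ± 2.64 FPKM (limma adjusted p = 0.00607 and 0.0227). Ssr3, a subunit of the translocon-associated protein complex of the endoplasmic reticulum, fell from 103 ± 0.85 to 36.7 ± 1.65 FPKM (limma adjusted p = 0.00607). The developmental regulator Mab21l2 fell by 2.05 on the log2 scale, the ubiquitin ligase gene Neurl3 by 1.84 and the nucleosome-binding gene Hmgn2 by 1.64. The adaptor gene Grap2 fell by 1.56, and Disc1, which encodes a scaffold protein of neurons, fell from 6.72 ± 0.98 to 1.68 ± 0.72 FPKM.

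Rpl30-ps9 (chromosome X, 105278637 to 105278981, GRCm38), a processed pseudogene of the ribosomal protein gene Rpl30, had the largest fitted fall, from 164 ± 80.8 to 3.37 ± 1.16 FPKM (limma adjusted p = 0.00445). It is uncertain, because Rpl30 and its pseudogenes can share reads. The copies named for Rpl30 summed to 320.9, 179 and 157 FPKM in si-NC and to 306, 37.8 and 42.8 FPKM in si-circCpsf6. Rpl30-ps10 alone read 229 FPKM in si-circCpsf6 replicate 1. Snora57, a small nucleolar RNA, fell from 2.88 ± 0.2 to 0.42 ± 0.39 FPKM (limma adjusted p = 0.0332). It overlaps Lbhd1 (log2 fold change -0.54, limma adjusted p = 0.237). Mab21l2 overlaps Lrba (-0.49, limma adjusted p = 0.119), and Hmgn2 has an annotated pseudogene, so reads of each could be shared.

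**Figure D1:**
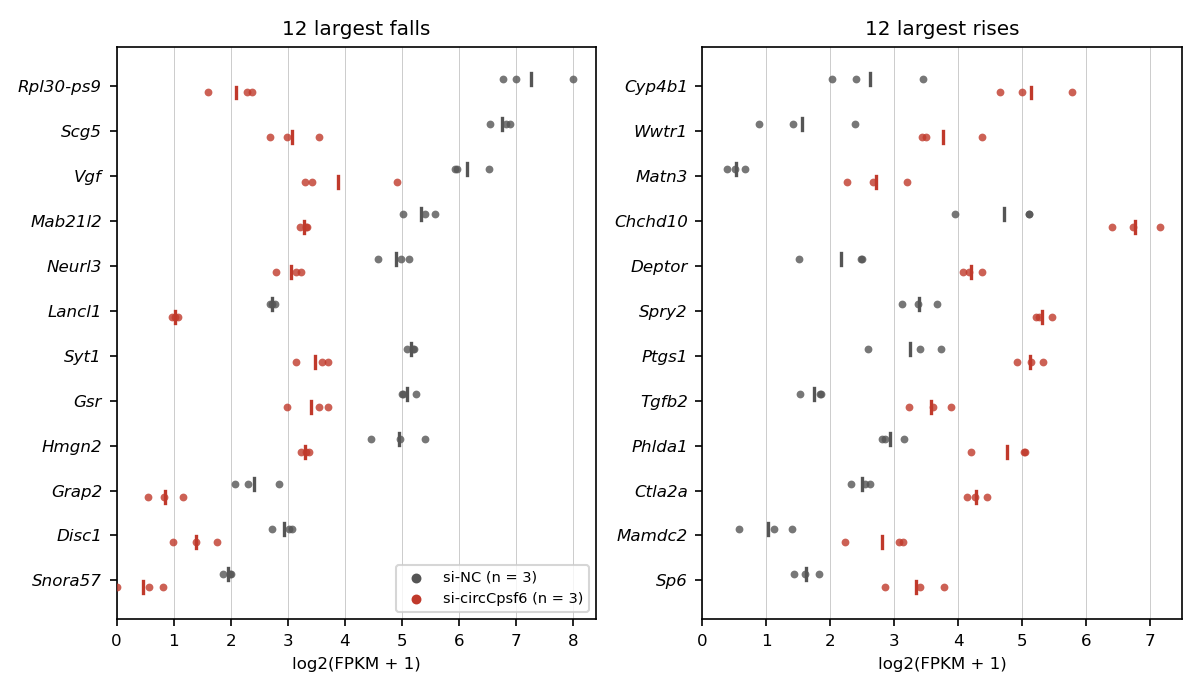
Expression of the 12 largest falls (left) and 12 largest rises (right) among called genes, as log2(FPKM + 1) on the horizontal axes. Each dot is 1 library, grey for si-NC (n = 3) and red for si-circCpsf6 (n = 3), and each vertical bar is the group mean. In every gene shown, the 3 red dots lie apart from the 3 grey dots.

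The genes that rose included regulators of growth factor signalling. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 14, 105891947 to 105896819), rose from 9.56 ± 1.99 to 38.9 ± 3.75 FPKM, a log2 fold change of 1.93 ± 0.17 (SE, n = 3; limma adjusted p = 0.00844). Deptor, an inhibitor of mTOR, rose from 3.69 ± 1.59 to 17.5 ± 1.94 FPKM, and Phlda1, an early target of growth factor signalling, rose from 6.72 ± 1.01 to 27.0 ± 8.29 FPKM (limma adjusted p = 0.0282 and 0.0284). Of secreted factors, Tgfb2 rose from 2.36 ± 0.42 to 11.1 ± 2.71 FPKM and Vegfc, a lymphangiogenic growth factor, from 3.45 ± 0.61 to 11.6 ± 1.2 FPKM (limma adjusted p = 0.0151 and 0.0134). Matrix genes also rose, Matn3 from 0.44 ± 0.15 to 5.79 ± 2.21 FPKM and Mamdc2 from 1.1 ± 0.59 to 6.3 ± 2.26 FPKM (limma adjusted p = 0.0179 and 0.0398). The transcriptional co-activator gene Wwtr1, which encodes TAZ, rose by 2.21 on the log2 scale and the transcription factor gene Sp6 by 1.72, with limma adjusted p values of 0.0465 and 0.0287. Among genes of metabolism, Cyp4b1 rose from 5.76 ± 3.67 to 36.3 ± 15.7 FPKM and the mitochondrial gene Chchd10 from 27.1 ± 10.9 to 110 ± 29.6 FPKM. The cyclooxygenase gene Ptgs1 rose from 8.93 ± 3.63 to 34.0 ± 4.93 FPKM and Bco1, which cleaves beta-carotene, from 3.77 ± 0.56 to 13.5 ± 1.07 FPKM. Ctla2a, an inhibitor of cysteine proteases, rose from 4.66 ± 0.6 to 18.6 ± 2.11 FPKM with the smallest p of the genes that rose (limma adjusted p = 0.00607). Vav3, a guanine nucleotide exchange factor, rose from 1.83 ± 0.38 to 7.95 ± 1.32 FPKM. Chchd10 overlaps Mmp11, Ctla2a overlaps Gm49391 and Sp6 overlaps Gm11532, and Cyp4b1 has 2 annotated pseudogenes, so reads of these could be shared.

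In all 219 called genes the 3 si-circCpsf6 values lay apart from the 3 si-NC values, as they did in 26.9% of the tested genes, where chance gives 10%. A called gene changed by at least 1 on the log2 scale in 77 rises and 54 falls, and 2633 genes had an unadjusted p under 0.05. The counts depended on the libraries kept and on the model: 7 rises and 6 falls were called without si-NC replicate 1, 15 and 17 without si-NC replicate 2, and 1 and 2 without si-NC replicate 3. They were 43 and 44 without si-circCpsf6 replicate 1, 7 and 15 without si-circCpsf6 replicate 2, and 9 and 11 without si-circCpsf6 replicate 3. With all 6 libraries kept and the replicate number as a block, 6 rises and 5 falls were called, 10 of them among the 219. In that fit 2781 genes had an unadjusted p under 0.05, so the drop was in adjusted calls alone. With 1 library left out, 2 (without si-NC replicate 3) to 60 (without si-circCpsf6 replicate 1) of the 219 were still called. In each of those fits all 219 genes kept their direction and an unadjusted p under 0.05. Because their groups did not overlap, no direction could have turned, and the genes were picked on these same libraries. Tested over all 30181 genes with any value above 0, 4 rises and 9 falls were called, and over the 10776 protein-coding genes, 245 and 192.

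Many of the genes that fell shared a sequence in their 3' untranslated regions (3' UTRs), found by a search made after the values were seen. Of 16353 heptamers searched in the longest annotated 3' UTR of 10668 tested genes, GCAGAAT had the most negative rank z, -13.59, with fold changes adjusted for UTR length, base composition and expression level. It stood in the 3' UTR of 44 of 95 called falls that could be searched (46.3%) and of 10.8% of the other genes. Of 112 called rises that could be searched, 8 carried it (7.1%). These shares and the medians below come from the genes it was picked on, so they describe the pattern and do not test it. In a search of 5805 genes on odd-numbered chromosomes alone it also had the most negative z (-10.6). On the 4862 genes of the held-out chromosomes its z was -8.51, ahead of -5.86 for the next heptamer. Those genes were read in the same libraries, so this repeats the pattern over genes and not over samples. Neurl3, Lancl1, Hmgn2, Syt1, Gsr and Ssr3 carried the heptamer among the falls named above, while Scg5, Vgf, Mab21l2, Disc1 and Grap2 did not. Of the rises named above, only Wwtr1 carried it. The median log2 fold change was -0.209 (95% bootstrap interval -0.249 to -0.175) for 285 genes with GCAGAATA and -0.102 (-0.124 to -0.076) for 904 genes with GCAGAAT alone. It was 0.012 (-0.004 to 0.031) for 2089 genes with only CAGAAT, -0.014 (-0.031 to 0.001) for 913 genes with CAGAATA, and -0.02 (-0.028 to -0.011) for 6477 genes with none of these. The shift was not limited to 3' UTRs. Among genes with no copy there, the median was -0.073 (-0.096 to -0.056) for 1254 genes with the heptamer in the coding sequence and -0.003 (-0.012 to 0.005) for those without. For 142 genes with it in the 5' UTR it was -0.085 (-0.131 to -0.017), against -0.009 (-0.017 to -0.002). These intervals resample genes. All of these medians, those by 3' UTR match included, use fold changes not adjusted for length, composition or expression level. With the 1189 genes carrying it in the 3' UTR left out, 71 rises and 45 falls were called, a setting also chosen after the values were seen.

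**Figure D2:**
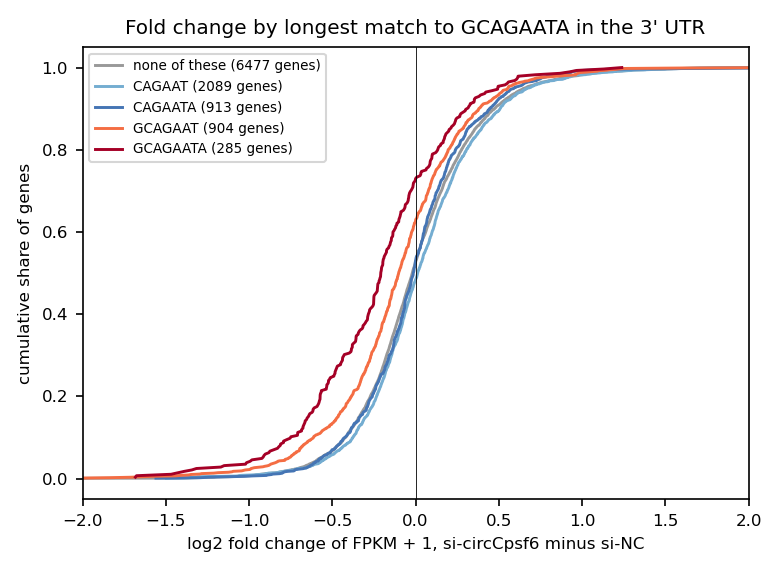
Cumulative share of genes (vertical axis) by log2 fold change of FPKM + 1, si-circCpsf6 minus si-NC (horizontal axis), with 1 line for each longest match to GCAGAATA in the 3' UTR. The line of the 285 genes with GCAGAATA lies furthest to the left (median -0.209) and that of the 904 genes with GCAGAAT lies between it and the rest (median -0.102).

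Gene lists fixed before the data were examined were compared with all other tested genes by camera, limma's competitive gene set test, with a preset correlation of 0.01 between genes. Of 31 lists with at least 5 tested members, 8 were called higher and 5 lower, and none was called with an estimated correlation, where the smallest adjusted p was 0.561. The list of ATF4 targets in the integrated stress response holds genes of amino acid synthesis and uptake beside stress regulators, Atf4 itself included. It was called higher, with 17 of 19 members above 0 and a median log2 fold change of 0.61 (camera adjusted p = 0.000173, and adjusted p = 0.659 with an estimated correlation). Its member Phgdh, the first enzyme of serine synthesis, rose from 49.5 ± 11.6 to 143 ± 39.2 FPKM (limma adjusted p = 0.0414), and 2 members passed when adjusted over the list alone. Phgdh has an annotated pseudogene, so reads of it could be shared. In the autophagy and lysosome list 17 of 20 members were above 0 (median 0.43, camera adjusted p = 0.000173, and adjusted p = 0.561 with an estimated correlation). Of these Wipi1, which acts in autophagosome formation, rose from 19.5 ± 4.72 to 64.9 ± 5.88 FPKM and Map1lc3a, a coat protein of autophagosomes, rose from 24.2 ± 3.89 to 61.1 ± 15.9 FPKM (limma adjusted p = 0.0151 and 0.0335). A count of 4 members passed when adjusted over the list alone.

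Cholesterol biosynthesis genes were called higher as a list, with 18 of 19 members above 0 and a median of 0.58 (camera adjusted p = 0.00132, and adjusted p = 0.726 with an estimated correlation). No single member passed over all genes or adjusted over the list alone: Insig1 read 39.2 ± 19.4 and 97.3 ± 35.2 FPKM, and Sc5d 6.78 ± 2.71 and 11.03 ± 1.3 FPKM, in si-NC and si-circCpsf6. The list was not called without si-NC replicate 2 (camera adjusted p = 0.195). Feedback genes of PI3K and MAPK signalling were called higher (13 of 18 above 0, median 0.41, camera adjusted p = 0.00332, and adjusted p = 0.561 with an estimated correlation). Spry2 passed over all genes, and 5 members passed adjusted over the list alone. All 6 tested neural progenitor and Notch genes were above 0 (median 0.48, camera adjusted p = 0.0113, and adjusted p = 0.561 with an estimated correlation). Among them were Vim at 56.0 ± 16.4 and 109 ± 18.3 FPKM and Hey1 at 1.68 ± 0.17 and 2.95 ± 0.63 FPKM, and 3 members passed only adjusted over the list alone.

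Extracellular matrix and adhesion genes were called higher (9 of 12 above 0, median 0.52, camera adjusted p = 0.00722, and adjusted p = 0.561 with an estimated correlation), but not without si-circCpsf6 replicate 1 (camera adjusted p = 0.0637). Fibronectin, Fn1, read 19.8 ± 5.26 and 61.0 ± 30.8 FPKM and Col4a2, a basement membrane collagen, 55.2 ± 17.8 and 115 ± 25.4 FPKM, and 3 members passed only adjusted over the list alone. Pdgfrb, 1 of 2 tested genes of the fibroblast marker list, rose from 1.12 ± 0.67 to 4.48 ± 0.35 FPKM (limma adjusted p = 0.0455). The other, Col1a1, named after its values were seen, read 1.84 ± 2.36 and 1.66 ± 1.82 FPKM (limma adjusted p = 0.999). The YAP, TEAD and TGF-beta target list was called higher (6 of 6 above 0, median 0.24, camera adjusted p = 0.0313, and adjusted p = 0.561 with an estimated correlation), with Tgfb2 its only member to pass over all genes or adjusted over the list alone. It was not called without si-NC replicate 2 (camera adjusted p = 0.114), si-NC replicate 3 (0.0706) or si-circCpsf6 replicate 1 (0.0801), nor with no filter on low values (0.158). Interferon and double-stranded RNA response genes were called higher (11 of 13 above 0, median 0.19, camera adjusted p = 0.0274, and adjusted p = 0.659 with an estimated correlation), but not without si-NC replicate 3 (0.0726) or si-circCpsf6 replicate 1 (0.114), nor with no filter on low values (0.269). Their member Oasl1, an interferon-induced gene, rose from 1.25 ± 0.34 to 4.54 ± 0.79 FPKM (limma adjusted p = 0.0287), and 3 members passed adjusted over the list alone.

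Of the lists called lower, genes of the G1/S transition and DNA replication had 21 of 24 members below 0 and a median of -0.61 (camera adjusted p = 0.000499, and adjusted p = 0.726 with an estimated correlation). No member passed over all genes or adjusted over the list alone. E2f2, a transcription factor of S-phase genes, read 12.7 ± 5.6 and 6.19 ± 0.93 FPKM, and Mcm4, a helicase subunit, 28.6 ± 9.55 and 15.2 ± 4.89 FPKM. The 3' UTR of E2f2 holds GCAGAAT. G2/M and mitosis genes were below 0 in 23 of 25 cases (median -0.22, camera adjusted p = 0.00872, and adjusted p = 0.793 with an estimated correlation). The list was not called without si-NC replicate 1 (0.292) or si-circCpsf6 replicate 1 (0.0823). The mitotic kinesin Kif20a, at 14.5 ± 2.03 and 8.18 ± 0.72 FPKM, passed only adjusted over the list alone, and its 3' UTR holds GCAGAATA. Of 2 tested replication-dependent histone genes, too few for the list test, H1f2 fell from 9.38 ± 1.25 to 3.21 ± 0.84 FPKM (limma adjusted p = 0.0287) and both passed adjusted over the list alone.

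All 6 tested genes of NF-kappaB signalling were below 0 (median -0.68, camera adjusted p = 0.00132, and adjusted p = 0.561 with an estimated correlation), but the list was not called with no filter on low values (0.0796). Nfkb1 read 4.15 ± 0.59 and 1.51 ± 0.56 FPKM and the inhibitor gene Nfkbia 46.2 ± 6.77 and 18.9 ± 10.0 FPKM (limma adjusted p = 0.0502 and 0.0858). A count of 4 members passed only adjusted over the list alone. Splicing factors of the SR and hnRNP families were below 0 in 19 of 21 cases (median -0.33, camera adjusted p = 0.00132, and adjusted p = 0.659 with an estimated correlation), with no member past the test over all genes or adjusted over the list alone. Srsf6 read 64.9 ± 4.73 and 40.7 ± 11.5 FPKM and Hnrnpk 74.1 ± 5.65 and 55.7 ± 4.31 FPKM. Both carry the 3' UTR heptamer, as do 3 members of the list in all. The sympathoadrenal neuroblast list, which marks the lineage of neuroblastoma, was called lower with 10 of 16 members below 0 (median -0.31, camera adjusted p = 0.0313, and adjusted p = 0.659 with an estimated correlation). In that list Chga, the granule protein chromogranin A, fell from 234 ± 12.97 to 110 ± 22.5 FPKM (limma adjusted p = 0.0335), and 5 members passed adjusted over the list alone. The list was not called without si-NC replicate 1 (0.139), si-NC replicate 3 (0.0843), si-circCpsf6 replicate 1 (0.0637) or si-circCpsf6 replicate 2 (0.0932), nor with the replicate block (0.0538).

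**Figure D3:**
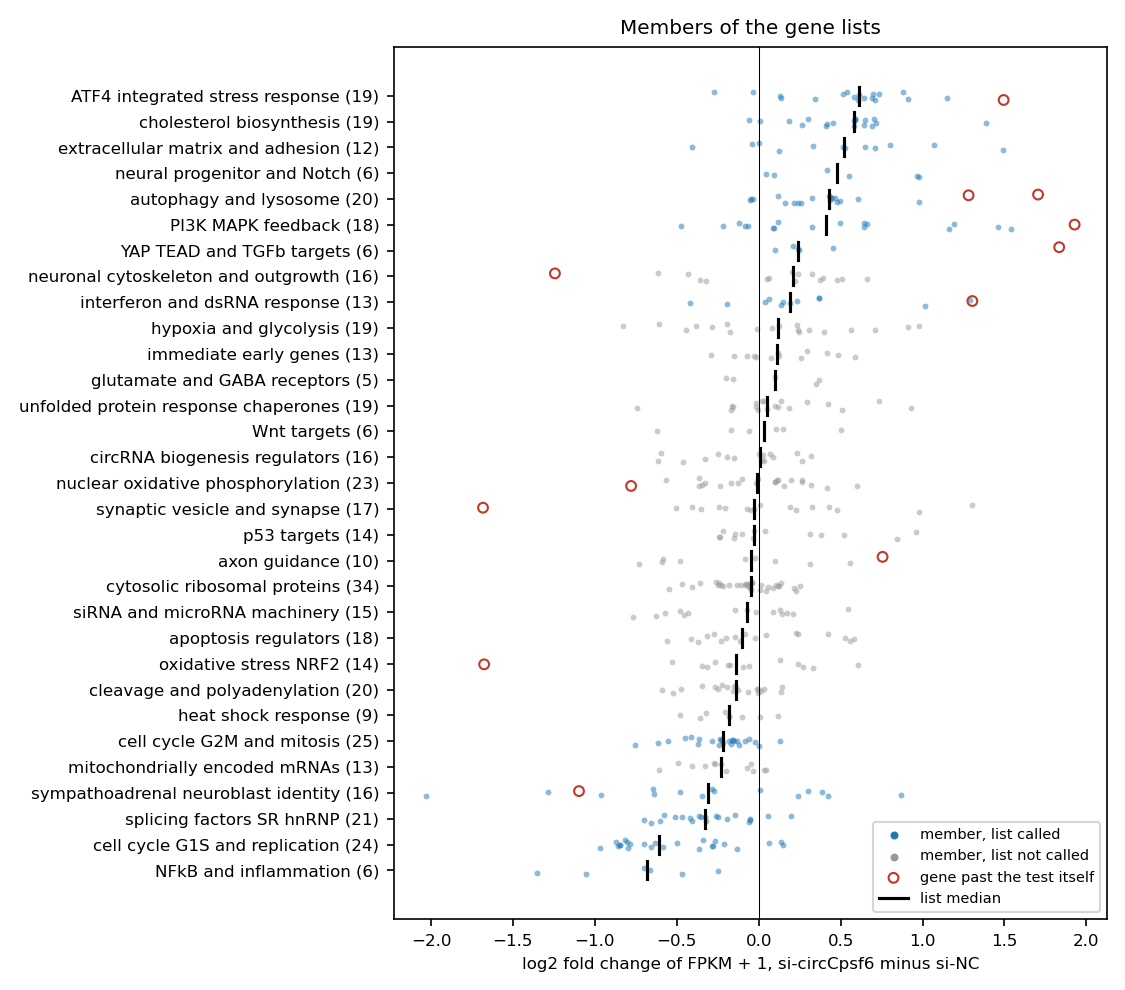
Log2 fold change of FPKM + 1, si-circCpsf6 minus si-NC (horizontal axis), of the members of the 31 tested lists, with the number of tested members in brackets. Each small dot is 1 gene, blue in lists called at the preset correlation and grey in the others. Open red circles are genes past the test over all genes, and black bars are list medians, from -0.68 (NF-kappaB) to 0.61 (ATF4 targets).

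A further 18 lists were not called. Cleavage and polyadenylation genes, the machinery Cpsf6 belongs to, had 16 of 20 members below 0 with a median of -0.14 (camera adjusted p = 0.064, and adjusted p = 0.654 with an estimated correlation). The list was called lower with no filter on low values (0.0066) and without si-circCpsf6 replicate 2 (0.0469). It had an adjusted p of 0.154 without the genes carrying the heptamer, a setting chosen after the values were seen. The 3' UTR of Cstf2t holds GCAGAATA, and this gene read 19.9 ± 1.74 and 12.8 ± 0.57 FPKM and was the 1 member to pass adjusted over the list alone (limma adjusted p = 0.0599 over all genes). In the list of siRNA and microRNA machinery (camera adjusted p = 0.302), Ago1 read 14.9 ± 1.6 and 8.35 ± 1.28 FPKM and Dicer1 10.4 ± 1.17 and 6.4 ± 0.22 FPKM. The 3' UTR of Dicer1 holds GCAGAAT. In that list 4 lower members and 1 higher member passed only adjusted over the list alone. Camera adjusted p was 0.606 for circRNA biogenesis regulators, 0.112 for the heat shock response, 0.366 for unfolded protein response chaperones, 0.444 for NRF2 targets and 0.348 for hypoxia and glycolysis. It was 0.606 for p53 targets, 0.928 for apoptosis regulators, 0.331 for immediate early genes and 0.928 for Wnt targets. For cytosolic ribosomal proteins it was 0.606, for mitochondrially encoded mRNAs 0.0744 and for nuclear oxidative phosphorylation genes 0.928, where Cox6c fell from 24.5 ± 0.86 to 13.9 ± 2.23 FPKM (limma adjusted p = 0.0455). Cox6c overlaps Vps13b, so reads of it could be shared. Some of these uncalled lists were called in other settings. Mitochondrially encoded mRNAs were called lower with no filter (0.0293), without si-NC replicate 1 (0.000717), with the replicate block (0.0472) and without si-circCpsf6 replicate 2 (0.0494), where the heat shock list was also called lower (0.0344). Without si-circCpsf6 replicate 1, cytosolic ribosomal proteins were called lower (0.000747) and unfolded protein response chaperones higher (0.0161). Hypoxia and glycolysis genes were called higher without si-NC replicate 1 (0.0073). Of the neuronal lists, the synaptic list that holds Syt1 had an adjusted p of 0.928, cytoskeleton and outgrowth 0.551, glutamate and GABA receptors 0.739 and axon guidance 0.928. Nefh, a neurofilament subunit, fell from 20.9 ± 1.44 to 8.57 ± 3.1 FPKM and the semaphorin gene Sema4d rose from 12.1 ± 1.19 to 21.1 ± 1.54 FPKM (limma adjusted p = 0.0499 and 0.0398). In 5 uncalled lists, circRNA biogenesis regulators, p53 targets, apoptosis regulators, synaptic genes and Wnt targets, the median, the mean and the direction of the test differed in sign.

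Markers of other cell types were mostly below the expression filter. The tested members were 1 of 8 astrocyte, 2 of 8 oligodendrocyte and Schwann cell, 2 of 9 fibroblast (given above) and 2 of 7 endothelial markers. No microglia or macrophage marker was tested, and the astrocyte list had Aldoc alone, at 5.77 ± 2.42 and 5.36 ± 4.32 FPKM. The oligodendrocyte and Schwann cell list had Mbp at 2.84 ± 0.39 and 1.82 ± 0.85 FPKM and Cnp at 5.32 ± 1.53 and 6.53 ± 1.3 FPKM, neither past the test. The 3' UTR of Mbp holds GCAGAATA. The endothelial list had Vwf, at 2.13 ± 0.25 and 0.69 ± 0.44 FPKM and past the test only adjusted over the list alone, and Pecam1 at 0.87 ± 0.25 and 1.44 ± 0.7 FPKM.

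Annotation terms given in the deposited table were tested in the same way. Of 2884 terms with 10 to 300 tested genes, 55 were called higher and 33 lower at the preset correlation, and none with an estimated correlation, where the smallest adjusted p was 0.914. At that setting 58 of the 2884 terms had an unadjusted p under 0.05. That is below a share of 0.05, which chance alone would give on average. Extracellular matrix (69 genes, median log2 fold change 0.38), signaling receptor activity (53 genes, 0.37) and basement membrane (45 genes, 0.37) were among the terms called higher, with camera adjusted p of 0.00252, 0.00252 and 0.00748. Ribosome biogenesis (94 genes, -0.19), nucleosome (24 genes, -0.33) and DNA replication initiation (21 genes, -0.53) were among the terms called lower, with camera adjusted p of 0.0098, 0.0121 and 0.0158. The number called lower was 8 without si-NC replicate 1, 63 without si-NC replicate 2, 5 without si-NC replicate 3 and 7 without si-circCpsf6 replicate 1, and the number called higher was 24 without si-circCpsf6 replicate 1.

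The authors' deposited table marks 607 genes as higher and 347 as lower, 550 of them with a q of at most 0.05, and its marked genes all have an absolute log2 fold change of at least 1. It includes 167 of the 219 genes called here. For Cpsf6 the authors' deposited table gives a log2 fold change of -0.12 and a p of 0.55.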

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

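All 219 called genes kept their direction and an unadjusted p under 0.05 in each fit in which they were tested. Their groups did not overlap, so leaving out a library or adding the block could not turn a direction. They were also picked on these same libraries, so neither outcome is a test of the calls. The counts of rises and falls were within 1.5 times 117 and 102 with median centring, quantile normalization, a pseudocount of 0.1, a mean of at least 5 FPKM and limma without the trend. They were 4 and 9 with no filter, 245 and 192 over protein-coding genes alone, 77 and 54 with an absolute log2 fold change of at least 1, and 71 and 45 without the genes carrying the heptamer (added after the data were seen). All of these but the fold change minimum change the number of genes tested, and the cause was not tested further. The authors' deposited table marks 607 and 347 genes, and its q of at most 0.05 holds for 465 and 325 tested genes. With 1 library left out, rises ranged from 1 (without si-NC replicate 3) to 43 (without si-circCpsf6 replicate 1) and falls from 2 to 44, from fits with fewer samples. The Cpsf6 log2 fold change ranged from -0.21 to 0.02 and never passed. Aldoc, not called, ranged from -0.80 to 0.32, the latter without si-circCpsf6 replicate 2. With an estimated correlation no list and no term was called in either direction: 0 against 8 lists higher, 0 against 5 lower, 0 against 55 terms higher and 0 against 33 lower. With 1 library left out, 6 to 9 lists were called higher and 4 to 7 lower, and 24 to 57 terms higher and 5 to 63 lower. Of 38 named genes that were called, 2 (Scg5 and Rpl30-ps9) were called without si-NC replicate 3.

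The replicate numbers are shared between the groups, but deviations from the group means correlated at 0.103, 0.129 and 0.084 for numbers 1 to 3, so the numbers were not taken to pair the samples. Each sample correlated best with its own number, a hint from the data and not the design. With the replicate block 6 rises and 5 falls were called, 10 of them among the 219, and the sympathoadrenal list was no longer called while mitochondrially encoded mRNAs were (camera adjusted p = 0.0538 and 0.0472). Depth is only estimated here, so what it limits in single genes is unknown.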

Other observations

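Genes of the secretory granule gave values in both directions. Beside Scg5, Vgf and Chga, which fell, Chgb (chromogranin B) read 1632 ± 510 and 426 ± 211 FPKM in si-NC and si-circCpsf6 (limma adjusted p = 0.065). Scg2 and Scg3, other granins, had log2 fold changes of 0.44 and 0.47, and Cpe, which trims prohormones, 0.35, none past the test (limma adjusted p = 0.273, 0.131 and 0.223). Syt4, a synaptotagmin, read 15.9 ± 2.93 and 42.5 ± 16.1 FPKM (limma adjusted p = 0.0692), while Syt1 fell. Chgb, Scg2, Scg3, Cpe and Syt4 were chosen after their values were seen.

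Of the tests below, those of the order of sites, of permutations on the held-out chromosomes and the count of genes over other splits were written after the result was seen, and the heptamer and the Rpl30 copies were noticed in the data they were tested on. For the falls that share GCAGAAT in the 3' UTR, the heptamer found on odd-numbered chromosomes was compared with all 420 permutations of its bases. On the held-out chromosomes it alone (0.24%) reached its z of -8.51, the next being -4.21. It already led all heptamers there, so that count was fixed beforehand. Its z was also already adjusted for UTR length, base composition and expression, so the count is no separate test of such a bias. The gap to the next permutation argues only against base composition alone as the source. No annotated Cpsf6 transcript holds more than 1 copy and 38.7% of genes of similar length have as many, which argues against release of a microRNA held at several sites of the circle (a circle with a single site was not tested). A candidate explanation is silencing through the seed of the transfected siRNA, whose guide would read ATTCTGC in DNA letters at positions 2 to 8. In the same libraries, the heptamer led all others on the held-out chromosomes. Among genes with a match there, medians fell in the predicted order. They were 0.006 for CAGAAT (95% bootstrap interval -0.028 to 0.03), -0.019 for CAGAATA, -0.1 for GCAGAAT and -0.188 for GCAGAATA (-0.251 to -0.102). Genes with no match, predicted to lie highest, had a median of -0.024 (-0.038 to -0.013), under CAGAAT and CAGAATA, with overlapping intervals. The predicted order was thus only partly met. These medians were not adjusted for UTR length, base composition or expression. Silencing through the seed stays open. The heptamer stands in 1 annotated Cpsf6 exon (chromosome 10, 117367979 to 117367985, minus strand, GRCm38), at bases 4 to 10 of 210 in an exon that starts GAAGCAGAATATGGTGGACATGAT and is exon 2 of 4 transcripts, where a guide laid across a back-splice junction into that exon would place it (by position alone, 1.66% of the longest transcript would). The siRNA and junction sequences were not analysed here. An effect of losing the circle stays open and untested, also for the rises and the 51 searched falls without the heptamer. The 10 splits of the 6 libraries are too few for a share under 5% (absolute z 13.59, highest of the others 11.75). GCAGAAT led in that other split too, and all the others mix the groups, so they are no reference for chance.

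The fall of Rpl30-ps9 could reflect reads moved between near-identical copies. The summed FPKM of Rpl30 and the pseudogenes named for it was 1.7 times higher in si-NC than in si-circCpsf6, and 5.43 times higher without si-circCpsf6 replicate 1. In si-circCpsf6 replicates 2 and 3 the sums (37.8 and 42.8 FPKM) lay below the si-NC range of 157 to 320.9 FPKM, so a move of reads among these copies alone would not account for those libraries. Copies under other names were not summed, so a move of reads to such copies stays open. In si-circCpsf6 replicate 1 the sum (306 FPKM) lay within that range and Rpl30-ps10 read 229 FPKM. That library leaves open how much of the fall was shared reads, because values per gene do not show which reads were shared.

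The 6 libraries make 10 splits into 3 and 3, too few for a share under 5%. Each split but the real one has libraries of both groups on both sides. A group difference then widens the spread within the sides and partly stays between them, so these splits are no reference for chance. For genes, 219 were called in the real split and at most 5 in another, so the real split alone reached its own count. For lists, 13 were called in the real split and at most 10 in another, so again only the real split reached its count. For terms, 88 were called in the real split and at most 126 in another, and 3 splits, the real one included, gave 88 or more.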
